A study of Populus tomentosa with 6 samples.

How the data were processed

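Leaves of Populus tomentosa were compared in 3 control and 3 heat-treated libraries. The deposited values are read counts per gene, whole numbers with one column per library and a different total in each, and are not scaled or pooled. The submitters' processing notes name CASAVA 1.8, TopHat2 2.0.12 and HTSeq 0.6.1, without their roles or order. The genome build, the annotation and its species, the strand setting and the treatment of reads that match several places are not given in the sources used here. Counts of near-identical gene copies and of overlapping genes are therefore uncertain. Groups and replicate numbers were taken from the sample titles, and each column of the table was matched to the sample whose title carries its name.

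The table lists 27209 genes by identifiers that begin with POPTR. The reference table used here, of a Populus tomentosa assembly (PTv2), holds 60139 genes under other locus tags, and 0 of the 27209 identifiers matched it. No gene names, functions, positions, lengths or GC contents were therefore used. The 40 gene lists fixed before the data were examined, which were patterns on gene names and descriptions and included markers of other leaf cell types, could not be applied, and no list was tested.

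Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its defaults (17458 kept and 9751 left out, the kept genes holding over 99.7% of the counts of each library), and libraries were scaled by trimmed mean of M-values (TMM) factors, which lay between 0.899 (heat library 3) and 1.17 (control library 2). A robust quasi-likelihood model with group as its only term was fitted to all 6 libraries, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Library totals between 6466647 and 8530622 set the precision of low counts. A count of 0 was taken to allow up to 3 counts over the 3 libraries of a group. Correlations and principal components used log2 CPM with a prior count of 2, computed here. Shares of counts were compared by two-sided exact permutation tests, which cannot go below p = 0.10 with 3 against 3.

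The rule for named genes was the largest fitted log2 fold changes among genes past the threshold with no overlap between the groups and at least 10 CPM in the higher group. Because neither the table nor the reference used here gave names, it was limited to 2 identifiers that rose and 2 that fell, as fixed for that case. Both rules, the main model and the alternatives below were set before the data were examined.

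Alternatives were DESeq2 size factors, upper quartile factors and library totals as scaling, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma 3.58.1 (voom), the replicate number as a block, thinning to the smallest library (6466647 counts), leaving out the 20 most abundant genes, an adjusted p below 0.01, a test against a 2-fold change, and leaving out each library. Same-numbered libraries were not treated as paired, since the labels do not say that the numbers mark shared plants or days. The deviations of same-numbered libraries from their group means correlated at 0.0487, 0.0998 and 0.178, all of them positive. On the second principal component (7.30% of the variance), control and heat library 3 lay at 42.4 and 43.3. Control and heat library 2 lay at -49.0 and -28.1, and control and heat library 1 at 5.04 and -13.7. A factor shared by replicate number is therefore not excluded.

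The tests were run on simulated data for the comparison of heat with control, in 5 simulations of the 17458 genes with 100 genes changed 2-fold and 100 changed 4-fold. The edgeR test recovered 10.0% of the 2-fold and 68.8% of the 4-fold changes, with median estimates of 1.01 and 2.02 on the log2 scale, and 8.80% of its calls were false. DESeq2 recovered 30.8% and 83.8%, with 29.2% of calls false, and limma (voom) 6.80% and 63.2%, with 7.41% false. The simulations changed far fewer genes than the 56.8% of tested genes called in the data. Adjustment over all genes is stricter when few genes change, so these recovered and false shares do not carry over to the data. Scaling with most genes changed was not simulated.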

Results

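Transcript abundance was measured by RNA sequencing in leaves of Populus tomentosa, the Chinese white poplar. Plants of both groups were raised for 75 days at 25 °C by day and 20 °C by night. Both had 16 h of light (350 µmol per m2 and s) and 8 h of dark. Plants kept at these temperatures formed the control group, and plants then heated to 45 °C formed the heat group. The heat group was first held at 37 °C for 2 h and then at 45 °C for 5 h, and each rise in temperature took 0.5 h. Each group held 3 libraries. The control libraries held 7345665, 6466647 and 8530622 gene counts, and the heat libraries held 7257659, 7564724 and 7761387. Of the 27209 genes in the table, 4229 had no count in any library and 17458 were abundant enough to be tested. A gene without counts may also be one whose gene model the reads did not match, since the species and version of the gene models are not given in the sources used here. Nothing in the sources used here says that the 3 libraries of a group came from separate plants, so the p-values measure only the spread between these libraries, which may be technical. The time of day at which control leaves were taken is also not given in those sources.

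The libraries separated by treatment. Across the tested genes, log2 CPM (counts scaled to a common library size) of 2 control libraries correlated with a mean Pearson r of 0.942 ± 0.0209 (SD over 3 pairs), and those of 2 heat libraries with a mean r of 0.940 ± 0.00515 (SD over 3 pairs). Between a control and a heat library the mean r was 0.649 ± 0.0312 (SD over 9 pairs, which share libraries). The highest of these between-group values, 0.704, lay below the lowest within-group value, 0.918. These correlations run across genes, which are not independent replicates, and carry no p-value. The first principal component held 80.5% of the variance and separated the groups, with control library 2 at -99.2 and heat library 2 at 98.0 as the library of each group nearest to the other group. No replicate pair was a repeat of one library, since their counts differed by 16.5 to 38.1 times the sampling noise (chi-square over its degrees of freedom).

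**Figure D1:**
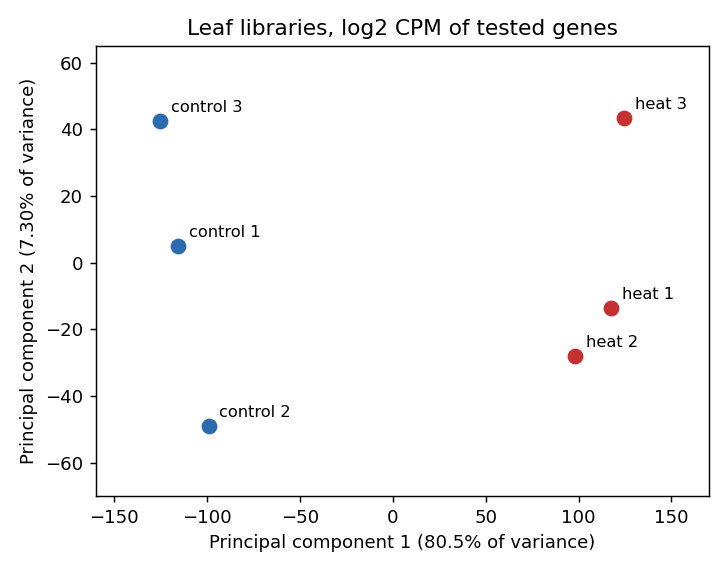
Positions of the 3 control (blue) and 3 heat (red) libraries on the first and second principal components of log2 CPM over the tested genes, in log2 units. The first component, with 80.5% of the variance, separates the groups, and control library 2 and heat library 2 lie nearest to the opposite group.

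The comparison of heated with control leaves asked which transcripts respond to heat stress. Of the 17458 genes tested, 4899 rose and 5018 fell in heated leaves, so that 56.8% of tested genes changed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). At least 2-fold changes were estimated for 3606 of the genes that rose and 3976 of those that fell. The median log2 change was 1.45 among genes that rose and -1.65 among genes that fell. The control and heat values did not overlap for 65.7% of all tested genes, against the 10% that chance gives for 3 libraries against 3. For the changed genes this share was 98.5%, which was largely set by selecting them on the same values. From the distribution of unadjusted p-values, 70.4% of the tested genes were estimated to differ between the groups. A stricter test, of whether the change itself exceeds 2-fold, called 2172 genes higher and 2329 lower. Scaling by library totals alone or by upper quartiles moved the median log2 change of all genes by -0.17 and -0.11, and the directions given here are relative to trimmed mean of M-values (TMM) scaling.

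**Figure D2:**
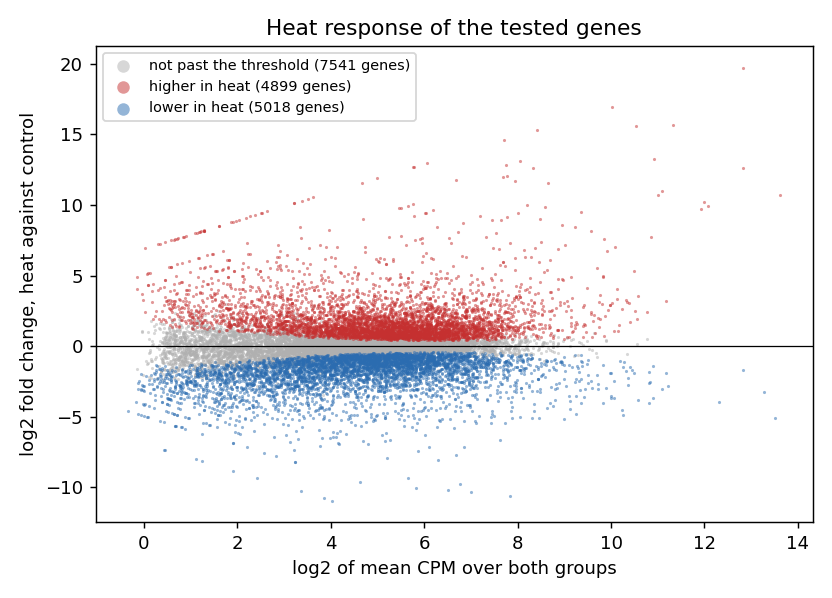
Each point is one of the 17458 tested genes, with the log2 of its mean CPM over both groups on the x axis and its log2 fold change (heat against control) on the y axis. Red points mark the 4899 genes higher in heat, blue points the 5018 genes lower in heat and grey points the 7541 genes not past the threshold.

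The named genes that rose, those with the highest fitted folds, went from no detected count in control leaves to some of the most abundant transcripts in heated leaves. POPTR_0012s02930 had 0 counts in each control library and 96358, 108527 and 101955 counts in the heat libraries. Its heat level was 14415 ± 250.2 CPM (SD, n = 3), or 1.36% ± 0.0662 of all counts (SD, n = 3). This was at least 113006-fold higher than in control leaves, taking 3 counts over the 3 control libraries together (0.128 CPM) as the highest level that a count of 0 allows (adjusted p = 2.21e-05, edgeR). POPTR_0013s09600 also had 0 counts in each control library and reached 2087 ± 75.3 CPM in heat (SD, n = 3), at least 16364-fold higher (adjusted p = 1.49e-05, edgeR). Among the tested genes, 47 had 0 counts in the 3 control libraries and a mean of at least 1 CPM in heat, and all 47 were called higher. The filter on low counts keeps such a gene only if all 3 heat libraries hold enough counts. These calls were therefore largely set by the filter, and genes it left out were not counted. The fold limits above cover counting error only.

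The named genes that fell had moderate mean levels in control leaves, with a wide spread, and were not detected in heated leaves. Both were lowest in control library 2. The named genes were ranked by fitted fold, which for a gene with 0 counts in one group depends on the prior count, so other genes may have changed by more. POPTR_0003s21940 had 414, 14 and 342 counts in control libraries 1 to 3, a mean of 32.6 ± 27.9 CPM (SD, n = 3), and 0 counts in each heat library. That is at least 232-fold lower in heat, taking 3 counts over the 3 heat libraries together (0.141 CPM) as the limit (adjusted p = 0.00910, edgeR). The limit rested on control library 1, without which it was 148-fold. It takes the control mean as exact, although control library 2, with 14 counts, lay much nearer to the heat level. The fitted log2 change of -10.93 had a standard error of 2.24. Without a filter on low counts this gene missed the threshold (adjusted p = 0.0567, edgeR). POPTR_0015s09020 had 189, 78 and 433 counts in the control libraries, a mean of 28.8 ± 20.2 CPM (SD, n = 3), and 0 counts in each heat library, at least 204-fold lower (adjusted p = 0.00130, edgeR). Without control library 3 this limit was 128-fold. Tested genes with 0 counts in all heat libraries and a mean of at least 1 CPM in control numbered 9. All 9 were called lower, which the filter on low counts again largely set. Neither the table nor the reference used here pairs these identifiers with gene names or functions, so further genes are described as groups.

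Larger changes went in both directions. Among genes past the threshold, 1566 rose and 1871 fell by at least 4-fold. These 4-fold counts were 1415 and 2100 under upper quartile scaling and 1341 and 2163 under library totals. At TMM scaling, 402 rose and 345 fell by at least 16-fold. More genes rose than fell by 16-fold under TMM scaling and under DESeq2 size factors (408 and 339). Upper quartile scaling gave 376 and 373, and scaling by library totals turned the order, with 365 and 384. For the largest changes, a fitted log2 change of at least 8 in size, the order did not depend on scaling. At TMM scaling 79 genes rose and 17 fell by this much. The counts were 80 and 17 with DESeq2 size factors, 76 and 18 under upper quartile scaling and 75 and 18 under library totals. Fitted folds of genes with 0 counts in one group depend on the prior count that the fit adds. A change below 2-fold was estimated for 1293 of the genes that rose and 1042 of those that fell.

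The most abundant transcripts differed between the groups. Of the 100 genes with the highest mean CPM in control leaves, 86 fell, 3 rose and 11 did not pass the threshold, with a median log2 change of -2.28. Of the 100 most abundant genes in heated leaves, 89 rose, 4 fell and 7 did not pass, with a median log2 change of 2.93, and 35 of them rose at least 16-fold. The lists shared 12 genes, against 0.573 expected for independent lists of this size among the tested genes. Rankings of one tissue are not independent, so this comparison does not show that the overlap was high. The overlap between replicates was not computed. Both lists were chosen by level in these libraries, so their directions are partly set by that choice. The most abundant gene of control leaves took 2.34% ± 0.842 of counts there (SD, n = 3) and 0.0612% ± 0.0273 in heat (SD, n = 3), a log2 change of -5.10. The most abundant gene of heated leaves took 2.35% ± 0.167 of counts there (SD, n = 3) and 0.00159% ± 0.000562 in control (SD, n = 3), a log2 change of 10.72. The 5 most abundant genes of control leaves all fell and the 5 most abundant of heated leaves, which include POPTR_0012s02930, all rose.

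Genes that changed held a large part of each library. Genes called higher in heat held 17.2% ± 2.13 of the tested counts in control (SD, n = 3) and 60.02% ± 2.18 in heat (SD, n = 3). Genes called lower held 53.2% ± 4.76 in control (SD, n = 3) and 13.5% ± 0.900 in heat (SD, n = 3). The groups did not overlap for either share (two-sided exact permutation test, p = 0.10, the smallest that 3 against 3 allows). These genes were selected on the same libraries, so the shares describe the size of the change and are not a separate test of it. The 10 most abundant genes of each library held 8.74% ± 2.51 of counts in control (SD, n = 3) and 9.13% ± 0.762 in heat (SD, n = 3), with p = 1 in the exact permutation test, a design that cannot show a difference at 0.05. Control library 2 held 5.85%, against 10.01% and 10.4% in control libraries 1 and 3, and without it the control mean was 10.2%, above the heat mean. Genes at or above 1 CPM numbered 17511 ± 273.9 in control (SD, n = 3) and 17071 ± 221.7 in heat (SD, n = 3), with p = 0.20 in the exact permutation test.

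**Figure D3:**
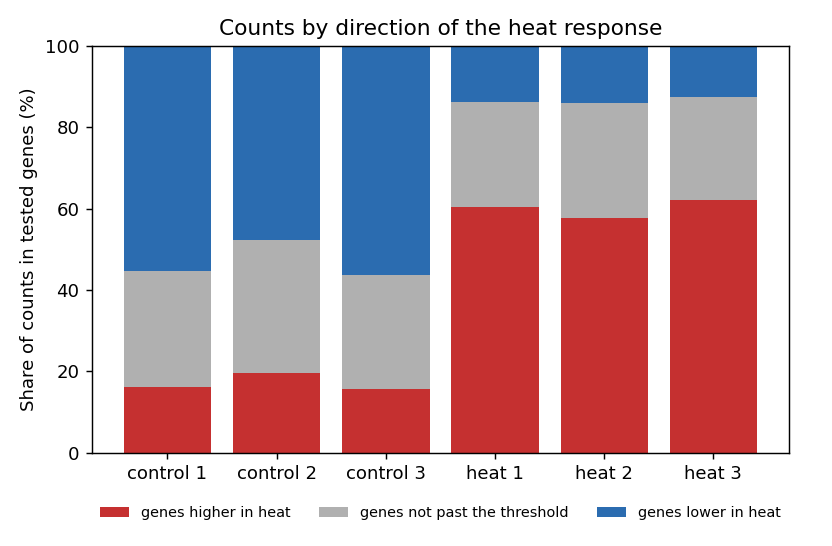
Share of each library's counts (y axis, percent of counts in tested genes) held by genes called higher in heat (red), genes not past the threshold (grey) and genes called lower in heat (blue). The share of genes called higher lies between 15.8% and 19.7% in the control libraries and between 57.7% and 62.05% in the heat libraries.

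The balance of rises and falls differed with abundance. Tested genes were divided into 4 equal classes by mean abundance over both groups. In the lowest class (1.08 to 9.18 CPM), 756 genes rose and 1190 fell, with a median log2 change of -0.36. In the second class 1001 rose and 1304 fell, with a median of -0.15 that became -0.25 under upper quartile scaling and -0.30 under library totals. In the third class 1405 rose and 1252 fell, with a median of 0.07 that became -0.04 under upper quartile scaling and -0.11 under library totals. In the highest class (56.6 to 12549 CPM) 1737 rose and 1272 fell, with a median of 0.24. Under upper quartile scaling the highest class held 1581 genes that rose and 1402 that fell, with a median of 0.10, and under library totals 1445 and 1417, with a median of 0.04. The share of genes that fell lay between 27.3% and 29.9% in each class, whereas the share that rose was 17.3% in the lowest and 39.8% in the highest. The lowest class held more genes that did not pass the threshold (2419) than the highest (1356).

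**Figure D4:**
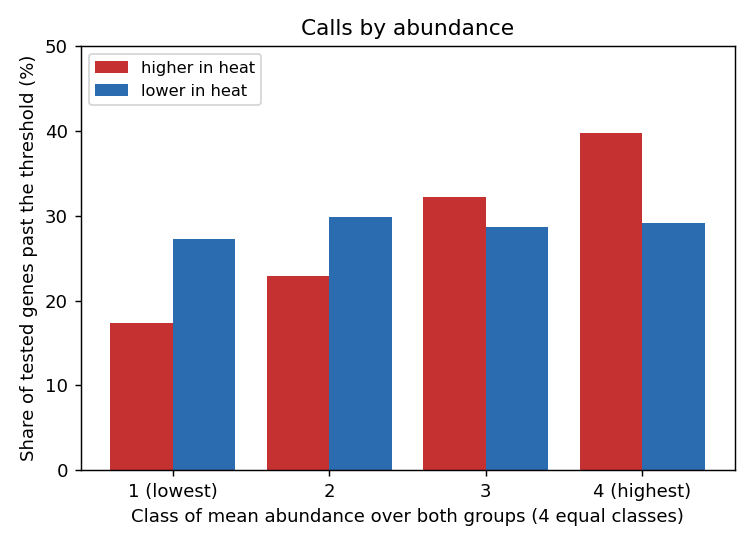
Percentage of tested genes (y axis) called higher (red) or lower (blue) in heat in 4 equal classes of mean abundance over both groups (x axis). The share called higher is 17.3% in the lowest and 39.8% in the highest class, while the share called lower stays between 27.3% and 29.9%.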

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

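All 4 named genes kept their direction in every alternative that tested them. With 0 counts in all libraries of one group their direction could not turn, so this says nothing about robustness. Of 71 gene-by-alternative values, 70 stayed past the threshold. The exception was POPTR_0003s21940 without a filter on low counts (adjusted p = 0.0567, edgeR). The number of changed genes stayed within 1.5 times the reported 9917 throughout. It was 9943 with DESeq2 size factors, 9568 with library totals, 10594 with DESeq2, 6914 at an adjusted p below 0.01 and 9949 with limma (voom), and between 8111 and 9728 with one library left out. The lowest of the latter, without control library 1, kept 79.99% of the calls in their direction. Leaving out control library 2 and heat library 2 together, a choice made after the data were seen, gave 9338. The share of higher calls was 49.4% as reported and 42.1% with library totals. With the replicate block 9561 genes were called, 93.1% of the reported calls kept, and the block moved no count by over 1.5 times. It ended no call among the named genes. Not every library correlated best with its own number. The count of genes changed at least 2-fold depended on how the threshold was applied. Testing against a 2-fold change gave 4501 genes, 2172 higher and 2329 lower, against 7582 by the estimate, because that test asks for an interval clear of the threshold. With a prior count of 0.5, the mean correlation fell from 0.940 to 0.930 within heat and from 0.942 to 0.935 within control. Between groups it fell from 0.649 to 0.625. The planned list tests were not run, since the reference used here named none of the identifiers. Depth limits the lowest class of abundance, where single genes rest on few counts.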

Other observations

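The tests of mixing and of shared neighbour response below were chosen after the results were seen; the others were set before their results were computed. Genes nearly silent at control temperature made up a visible part of the heated transcriptome. A set of 28 genes with at most 3 counts in control libraries 1 and 3 together and at least 50 CPM in heat held a mean of 241070 counts per heat library and 15, 24 and 11 counts in control libraries 1, 2 and 3. The opposite set, with at most 3 counts in heat libraries 1 and 3 and at least 50 CPM in control, held 8 genes, with a mean of 11482 counts per control library and 8, 23 and 8 counts in heat libraries 1, 2 and 3. The spread between replicates was similar in size, with a common biological coefficient of variation of 0.299 in control and 0.321 in heat, a difference that was not tested.

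The real grouping called 9917 genes, and the highest of the other 9 of the 10 splits of the 6 libraries called 0 by edgeR, with 361 genes at an unadjusted p under 0.05 against 10868 for the real one. Each other split puts control and heat libraries on both sides, which widens the spread within its groups, so low counts there follow from the design and say little about chance. For changes of at least 2-fold the counts were 7582 and 0. In both cases 1 split, the real one, gave a count as large, and 10 splits are too few for a share under 0.05.

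Of the control libraries, library 2 lay furthest toward the heat libraries. Its difference from control library 1 correlated across genes with the heat effect measured against control library 3 at r = 0.257, and its difference from control library 3 with the heat effect measured against control library 1 at r = 0.226, a mean of 0.241. The like value between control libraries 1 and 3 was 0.021, and no spread for unchanged libraries was computed. The measure changes sign when 2 libraries of a group are swapped. In each group some library must therefore come out toward the other group, and such a lean by itself does not call for a cause. Heat library 2 lay toward the controls in the same measure (mean r = 0.208). RNA or reads from heat libraries mixed into control library 2 are argued against by the 28 heat genes above, which stood there at 0.0093% of their heat level. The 8 control genes stood in heat library 2 at 0.207% of their control level, so a trace of control reads there is not excluded. Lower depth is argued against by thinning all libraries to one total, which left the mean r at 0.2411. A milder or later state of the sampled plants, or handling, stays open, as does a factor shared by the libraries numbered 2. Ordinary spread between replicates stays open too. No biological explanation was tested because the labels distinguish nothing within a group.

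The median log2 fold change was 0.60 higher in the highest of the 4 classes of abundance than in the lowest. Unequal depth between the groups is argued against by their totals, 22342934 counts in control and 22583770 in heat. With totals this close, thinning all libraries to one total could change little, and it left the difference at 0.5983. Ranking genes by their mean log2 CPM, an average on the log scale instead of the count scale, gave 0.6487, which argues against the way abundance was averaged. The difference was 0.54 under library totals, 0.56 under upper quartile scaling and 0.61 with DESeq2 size factors. A heat response that differs between abundance classes may remain, as may a length or GC bias, which was not tested because no gene models were used here.

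Genes with adjacent identifier numbers changed alike. Over 8375 pairs of tested genes whose numbers differ by the step of 10, the log2 fold changes correlated across pairs at r = 0.1501 (Spearman rho = 0.105; permutation p = 1e-05 for each, one-sided, the smallest that 100000 resamples give), and in the order of tested genes, whatever the step between their numbers, r was 0.10 between next neighbours, 0.039 at lag 2, 0.023 at lag 5 and -0.0016 at lag 20. Both members rose at least 4-fold in 133 pairs against 67.4 expected from independent genes, both fell in 135 against 96.2, and they went opposite ways in 120 against 161. Reads shared between near-identical neighbours may contribute. Of the 268 pairs that changed the same way, 33.58% (95% exact binomial interval 27.95 to 39.6) differed in fold by more than 2 standard errors. A gene can belong to 2 pairs, so the pairs are not independent and the interval may be too narrow. The share lies between what sharing and no sharing predicted, so the explanation stays open. That the identifier numbers follow the order along a chromosome is an assumption, and tandem gene copies with a common heat response are a hypothesis that needs their sequences.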
